A study of Mus musculus with 24 samples.

How the data were processed

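Small RNA was measured in BV2 mouse microglial cells and in the EVs they released, in controls and after 72 h with LPS (100 ng/mL), IL-10 (50 ng/mL) or TGF-β (50 ng/mL), with 3 libraries in each of 8 groups. Per the labels, RNA was extracted with miRNeasy kits, from 20 µL of EVs for the vesicle samples, and eluted in 40 µL for cells and 20 µL for EVs. Libraries were made with the SMARTer smRNA-seq kit and 18 PCR cycles and sequenced on a HiSeq X with reads of 150 bases, with 40 M reads planned per library. The deposited values are counts of reads per microRNA precursor, whole numbers that were not normalized. The aligner, the annotation, the genome build and any filter are not given in the sources used here. The submitters' processing notes name DESeq2, without a version. The series holds 8 deposited tables. Of these 6 were used, and 2 were identical to a used one. The control columns of a compartment were the same in its tables and were used once. The tables list 1187 precursors, of which 295 were at 0 in every library, and they do not separate the mature arms.

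Library totals were 185400 to 409969 counts in cells and 15071 to 28727 in EVs, and 402 to 449 and 178 to 312 precursors had at least 1 count. A floor of 3 counts corresponds to 0.000732% to 0.00162% of a cell library and 0.0104% to 0.0199% of an EV library. For precursors with 1 to 3 counts over a group, ratios are given with a 95% counting interval from an exact binomial test, and for those at 0 as a bound from a floor of 3 counts over the group. Both use counts summed over the libraries of a group and leave out the spread between libraries, so the intervals are too narrow for a difference between groups.

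Comparisons used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with TMM normalization factors, filterByExpr with a minimum count of 10, and edgeR's quasi-likelihood F test, which is two-sided. Treatments were compared with control, and LPS with the mean of IL-10 and TGF-β, in 1 fit per compartment (8 residual degrees of freedom). Control EVs were compared with control cells, and each treatment effect in EVs with that in cells, in 1 fit over the 24 libraries (16 residual degrees of freedom). These are 12 comparisons. Adjusted p-values are Benjamini-Hochberg values over the precursors tested in a comparison, and a value under 0.05 was called. Fold changes are edgeR estimates, and their SE comes from the quasi-likelihood F statistic. Normalised CPM are counts scaled by library total and TMM factor, with the factors of the fit concerned.

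Before the data were examined, 22 lists of precursors were fixed: precursors induced through Toll-like receptor 4 and NF-kB, anti-inflammatory or alternative activation, TGF-β responsive, 9 families and smaller clusters, myeloid, the Sfmbt2 and Dlk1-Dio3 clusters, EV cargo, markers of other cell types and precursors overlapping rRNA, tRNA or snoRNA. Lists with at least 3 tested members were tested with camera (preset correlation 0.01) on voom values. Camera was repeated with a correlation estimated from the data, and fry was run as a self-contained test. Of 156 list tests camera called 30, camera with an estimated correlation 0, fry 43, and camera and fry together 24. The lists for the miR-99b/let-7e/miR-125a cluster, miR-181, mir-221 with mir-222, the Dlk1-Dio3 cluster, serum, red cell and liver, muscle and epithelium had too few tested members in every comparison. The named precursors were also fixed by rule beforehand. The rule took the 10 with the smallest p in each direction among called precursors whose 3 libraries lay apart from the 3 others, and the 5 smallest in each direction where fewer than 10 passed. It added mir-155, mir-146a, mir-21a, mir-124, mir-223, mir-132, mir-147, let-7a, mir-181a and mir-29a in treatment comparisons and up to 4 members of each list. In EVs against cells it also added the 5 most abundant of each compartment. For the interactions and for LPS against the mean of the cytokines it took the 5 with the smallest p in each direction.

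Alternatives fixed before the data were examined were DESeq2's size factors, library totals alone, no filter on low counts, a mean of at least 50 counts, the Wald test of DESeq2 1.42.0, a robust prior, each library left out in turn, only the groups compared, and EVs minus cells averaged over the 4 treatments. Keeping 1 copy per set of numbered copies and leaving out mir-6236 and mir-6240 were added after the data were seen. Overlap between treatments that share controls was set against 100 simulations of unchanged groups. The procedure was tested on simulated data with 25 simulations of 200 changed precursors among 1187. On average 253 precursors passed the filter for LPS in cells, 72.9 for LPS in EVs and 238 for EVs against cells. Recovery was counted only among changed precursors that passed it. At a log2 change of 2 it was 98.4% for LPS in cells, 20% for LPS in EVs and 77.1% for EVs against cells. At a log2 change of 1 it was 87.0%, 2.55% and 34.5%, and false calls were 4.03%, 2.5% and 2.79% of calls. For EVs against cells the EV libraries were simulated with the composition of control cells. Recovery with the real composition of the EVs was therefore not measured in that comparison. The median SE of a log2 fold change was 0.189 for LPS in cells, 0.814 for LPS in EVs and 0.931 for EVs against cells. Positions of precursors in GRCm38 served only to find neighbours. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.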

Results

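Small RNA was sequenced from BV2 cells, an immortalised mouse microglial cell line, and from the extracellular vesicles (EVs) that these cells released. The cultures were controls or had received lipopolysaccharide (LPS, a bacterial ligand of Toll-like receptor 4, 100 ng/mL), interleukin-10 (IL-10, 50 ng/mL) or transforming growth factor beta (TGF-β, 50 ng/mL) for 72 h. Each of the 8 groups had 3 libraries, 24 in all, and the deposited tables give whole counts for 1187 microRNA precursors. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Cell libraries held 185400 to 409969 counts, and EV libraries 15071 to 28727. The median total of the cells was 18.4 times that of the EVs. A count of 0 allowed a share of up to 0.00162% of the counts in the shallowest cell library and up to 0.0199% in the shallowest EV library. These limits cover counting error, since PCR copies were not separated from molecules. At 5 or more counts in at least 2 of 3 libraries, 272 precursors were detected in control cells and 261, 273 and 267 after LPS, IL-10 and TGF-β. In the EVs the corresponding numbers were 72, 121, 64 and 63. Thinned to 15071 counts per library they were 144, 130, 144 and 136 in cells and 69, 92, 62 and 61 in EVs.

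The 13 precursors named let-7, whose mature products restrain proliferation in many cell types, took 49.5 ± 1.26% of the counts in control cells (SD, n = 3). They took 38.9 ± 1.12% after LPS, 57.2 ± 2.28% after IL-10 and 51.7 ± 2.39% after TGF-β. Shares within a library depend on each other, and mir-5099 took 12.7 ± 1.53% in control cells and 21.2 ± 1.66% after LPS. With TMM factors let-7a-1 was not called after LPS in cells and the let-7 list did not pass, as given below. The lower share alone therefore does not show a loss of let-7. Control EVs were dominated by mir-6236, an annotated precursor listed beforehand among those that overlap other non-coding RNAs, at 74.5 ± 1.17% of counts. In control cells mir-6236 took 0.796 ± 0.0186%. Its share of EV counts was 57.2 ± 7.82% after LPS, 73.0 ± 10.2% after IL-10 and 73.4 ± 4.88% after TGF-β. The let-7 share of the EVs was 4.36 ± 0.789% in controls, 10.4 ± 2.44% after LPS, 4.88 ± 3.85% after IL-10 and 3.38 ± 0.00379% after TGF-β. IL-10 EV library 1, with 17724 counts, had 9.326% let-7 and 61.19% mir-6236, within the ranges of the LPS EV libraries (7.647 to 12.33% and 49.91 to 65.46%). Replicates of one group differed by more than counting noise in each of the 24 pairs, with a chi-square over degrees of freedom of 4.53 to 19.4 in cells and 5.18 to 33.5 in EVs. Pearson's r between replicates, across precursors, was 0.898 to 0.946 in cells and 0.045 to 0.425 in EVs. It covers log2 CPM of every precursor with a count in either library, so precursors near the floor weigh heavily in the shallow EV libraries. Precursors are not independent replicates.

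**Figure D1:**
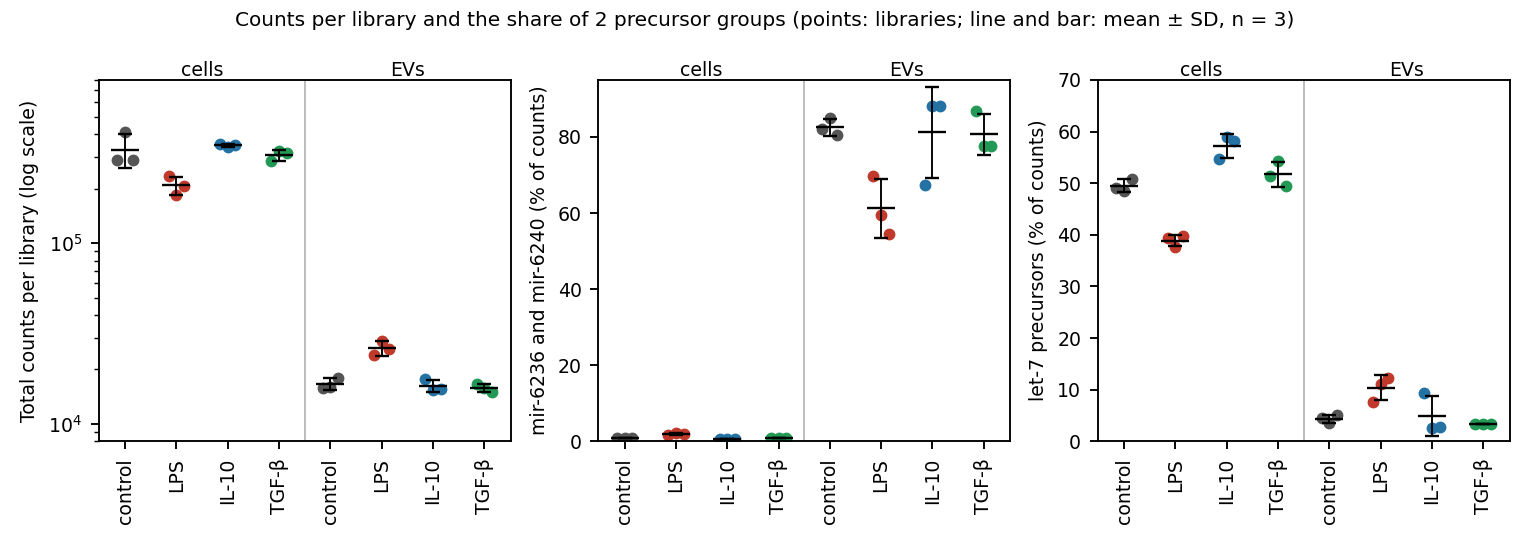
Total counts per library (log scale), the percentage of counts from mir-6236 and mir-6240, and the percentage from let-7 precursors, by treatment in cells and EVs. Points are libraries, and lines with bars are the mean and SD of 3 libraries. The pair mir-6236 and mir-6240 took 82.5% of control EV counts and 61.2% of LPS EV counts on average, against 0.93% in control cells.

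LPS in cells was compared with control to find the precursors of an inflammatory state. mir-146a, a feedback inhibitor of NF-kB signalling through Irak1 and Traf6, rose from 975 ± 97.7 to 48386 ± 4102 normalised CPM (SD, n = 3 each). This was a 49.6-fold rise (log2 5.63 ± 0.18 SE, edgeR adjusted p = 2.29e-17). Its relative mir-146b rose 22.5-fold (4.49 ± 0.17), and mir-155, processed from the Bic transcript of activated macrophages, rose 16.7-fold, from 21.7 ± 4.76 to 365 ± 48.9 normalised CPM (edgeR adjusted p = 1.4e-10). mir-21a rose 4.06-fold, and mir-132, at 7.29 ± 4.68 normalised CPM in controls, rose by a log2 of 2.32 ± 0.66 (edgeR adjusted p = 0.0107). On the falling side, the hypoxia-induced mir-210 went from 2602 ± 110 to 345 ± 188 normalised CPM (log2 -2.93 ± 0.33).

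All 5 tested members of the fixed list of precursors induced through Toll-like receptor 4 and NF-kB rose, also when adjusted over the list alone (camera adjusted p = 1.81e-07; adjusted p = 0.23 with an estimated correlation). The 4 miR-29 precursors, known regulators of collagen genes, rose as well: mir-29b-2 by a log2 of 1.45, mir-29b-1 by 1.28, mir-29a by 0.74 and mir-29c by 0.71. Their camera adjusted p was 0.0223, and the adjusted p was 0.554 with an estimated correlation. With library totals mir-29a (0.32) and mir-29c (0.29) were no longer called. Both members of the list of mir-221 and mir-222, regulators of the cell cycle inhibitor p27, rose, mir-222 by 2.29 ± 0.13 and mir-221 by 1.66 ± 0.14. Of 12 tested members of the miR-17-92 cluster and its paralogs, 5 rose, among them mir-19a (0.48) and mir-92a-1 (0.44). The same 5 calls stood when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.25). Under scaling by library totals mir-92a-1 stood at 0.02 and mir-19a at 0.07, both no longer called. Among 9 myeloid precursors 4 rose, such as mir-342 (1.73), and 2 fell, mir-511 (-1.78), which lies in an intron of the mannose receptor gene, and mir-223 (-0.66). The myeloid list did not pass as a whole (camera adjusted p = 0.127), with 4 higher and 4 lower when adjusted over the list alone. The Sfmbt2 cluster, a large intronic repeat of rodent precursors, had 6 of 67 tested members higher and 5 lower, 5 and 4 when adjusted over the list alone, with a downward camera adjusted p of 0.0223 (adjusted p = 0.554 with an estimated correlation). Many of its members are numbered copies that may share reads, and the preset correlation takes them as almost independent. The camera p of this list may thus be too small in every comparison.

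Precursors that overlap rRNA, tRNA or snoRNA rose in 5 of 6 cases, the same number adjusted over the list alone, with mir-6240 at 2.25, mir-1983 at 2.08, mir-6236 at 1.28 and mir-664 at 0.92 on the log2 scale (camera adjusted p = 0.00107; adjusted p = 0.488 with an estimated correlation). Other large changes were mir-320, whose precursor bypasses Drosha, at 3.07 ± 0.18, mir-7a-2 at 1.67 ± 0.18, mir-326 at -2.07 ± 0.23, mir-700 at -1.64 ± 0.19 and mir-351 at -1.58 ± 0.18. mir-181a-2 fell by 1.52 on the log2 scale and mir-181a-1 by 1.34, and numbered copies of this kind cannot be counted as independent. let-7a-1 was at 0.10 ± 0.13 (edgeR adjusted p = 0.596). mir-124 and mir-147 had too few counts to be tested. The remaining lists did not pass: the camera adjusted p was 0.0664 for precursors often reported as EV cargo, 0.275 for the miR-23/27/24 clusters, 0.458 for anti-inflammatory or alternative activation, 0.835 for the miR-15/16 family, 0.87 for TGF-β responsive precursors, 0.924 for let-7 and 0.937 for the miR-30 family. In total 54 of 259 tested precursors were higher and 29 lower after LPS, and 123 had no overlap between the 3 LPS and the 3 control libraries, 47.5% where chance gives 10%. The split was 50 higher and 47 lower with DESeq2's size factors, and 30 higher and 101 lower with library totals, which moved the median of all tested precursors from 0.09 to -0.32.

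IL-10 in cells, an anti-inflammatory cytokine, gave fewer calls. mir-21a rose 3.74-fold, from 1415 ± 181 to 5289 ± 51.6 normalised CPM (log2 1.90 ± 0.14, n = 3 each; edgeR adjusted p = 9.48e-10), and mir-342, from an intron of Evl, rose 2.91-fold (1.54 ± 0.22). mir-222 rose by a log2 of 0.76 ± 0.13, mir-146b by 0.68 ± 0.15 and mir-146a by 0.65 ± 0.15. The cluster members mir-92a-2 (-0.95 ± 0.13), mir-92a-1 (-0.91 ± 0.13) and mir-17 (-0.53 ± 0.14) fell, as did mir-210 (-1.12 ± 0.28), mir-703 (-0.82 ± 0.22) and mir-92b (-0.68 ± 0.20). let-7a-1 (0.48 ± 0.13), let-7e (0.49 ± 0.14) and let-7f-1 (0.44 ± 0.13) were among 5 of 13 members of the fixed let-7 list that rose; this list holds mir-98 and leaves out let-7j.

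By list, 3 of 5 precursors induced through Toll-like receptor 4 and NF-kB rose (4 when adjusted over the list alone; camera adjusted p = 0.000193, adjusted p = 0.299 with an estimated correlation). For the let-7 family the adjusted p was 0.000682 with camera and 0.47 with an estimated correlation, with 8 higher when adjusted over the list alone. The miR-17-92 list had 3 of 12 members lower (4 adjusted over the list alone; camera adjusted p = 0.00547, adjusted p = 0.299 with an estimated correlation). Among 9 myeloid precursors 3 rose, mir-21a, mir-342 and mir-146a (4 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.299 with an estimated correlation). Of 6 members of the miR-23/27/24 clusters 1 rose, mir-27b at 0.51 ± 0.14 (4 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.47 with an estimated correlation). The TGF-β responsive list had 1 of 11 members higher, mir-21a (7 adjusted over the list alone; camera adjusted p = 0.000544, adjusted p = 0.299 with an estimated correlation). The list for anti-inflammatory or alternative activation had 2 of 8 higher, mir-222 and mir-146a (5 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.299 with an estimated correlation). mir-155 stood at 0.73 ± 0.39 (edgeR adjusted p = 0.243), mir-132 at 1.59 ± 0.65 (0.12) and mir-223 at 0.08 ± 0.20 (0.834).

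In all, 14 precursors were higher and 6 lower after IL-10, and 83 (32%, chance 10%) had groups that did not overlap. With DESeq2's size factors 13 were higher and 10 lower, and with library totals, which moved the median from 0.05 to -0.17, 11 and 18, without mir-27b (0.29). The count fell from 20 to 5 without control library 1, to 13 without control library 3, to 7 without IL-10 library 2 and to 9 without IL-10 library 3.

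TGF-β in cells, a cytokine that maintains the microglial phenotype, lowered mir-21a and mir-222, which LPS and IL-10 raised. mir-223, a myeloid precursor, fell from 240 ± 41.2 to 75.1 ± 29.6 normalised CPM (log2 -1.70 ± 0.25, n = 3 each; edgeR adjusted p = 4.14e-05). mir-210 fell by 1.88 ± 0.30 on the log2 scale, mir-222 by 1.05 ± 0.14 and mir-21a by 1.03 ± 0.14. The X-linked neighbours mir-503 (-1.40 ± 0.33), mir-351 (-1.06 ± 0.15) and mir-322 (-0.69 ± 0.14) fell, as did mir-326 (-0.78 ± 0.19), while mir-450b, within 10 kb of these neighbours and chosen after its value was seen, stood at 0.12 ± 0.50 (edgeR adjusted p = 0.908). mir-504 rose 4.31-fold, from 14.4 ± 3.60 to 64.0 ± 25.2 normalised CPM (2.11 ± 0.45).

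Other precursors that rose were let-7j (0.80), let-7i (0.74), mir-872 (0.69), mir-23b (0.60), mir-23a (0.58), mir-93 (0.56), the p53 target mir-34a (0.56) and mir-744 (0.51). Of 6 members of the miR-23/27/24 clusters 2 rose, and 3 did so adjusted over the list alone (camera adjusted p = 0.00739; adjusted p = 0.898 with an estimated correlation). Of 9 myeloid precursors 2 fell, mir-223 and mir-21a, and 5 did so adjusted over the list alone (camera adjusted p = 0.00739; adjusted p = 0.898 with an estimated correlation). The let-7 list, which leaves out let-7j, had 1 of 13 members higher (let-7i), also adjusted over the list alone, with a camera adjusted p of 0.0258 (adjusted p = 0.898 with an estimated correlation). The TGF-β responsive list had 1 of 11 higher, mir-23a, and 1 lower, mir-21a, the same adjusted over the list alone (camera adjusted p = 0.647). mir-146a was at 0.28 ± 0.16 (edgeR adjusted p = 0.282), mir-155 at -0.43 ± 0.48 (0.611) and mir-132 at 0.23 ± 0.81 (0.88). The totals were 9 higher and 8 lower of 259, and 67 precursors (25.9%, chance 10%) had groups that did not overlap. DESeq2's size factors gave 8 higher and 17 lower, and library totals, which moved the median from 0.09 to -0.06, gave 5 and 19. mir-34a was not called under either (0.49 and 0.40), nor mir-93 (0.41), mir-744 (0.35) and mir-872 (0.55) with library totals.

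**Figure D2:**
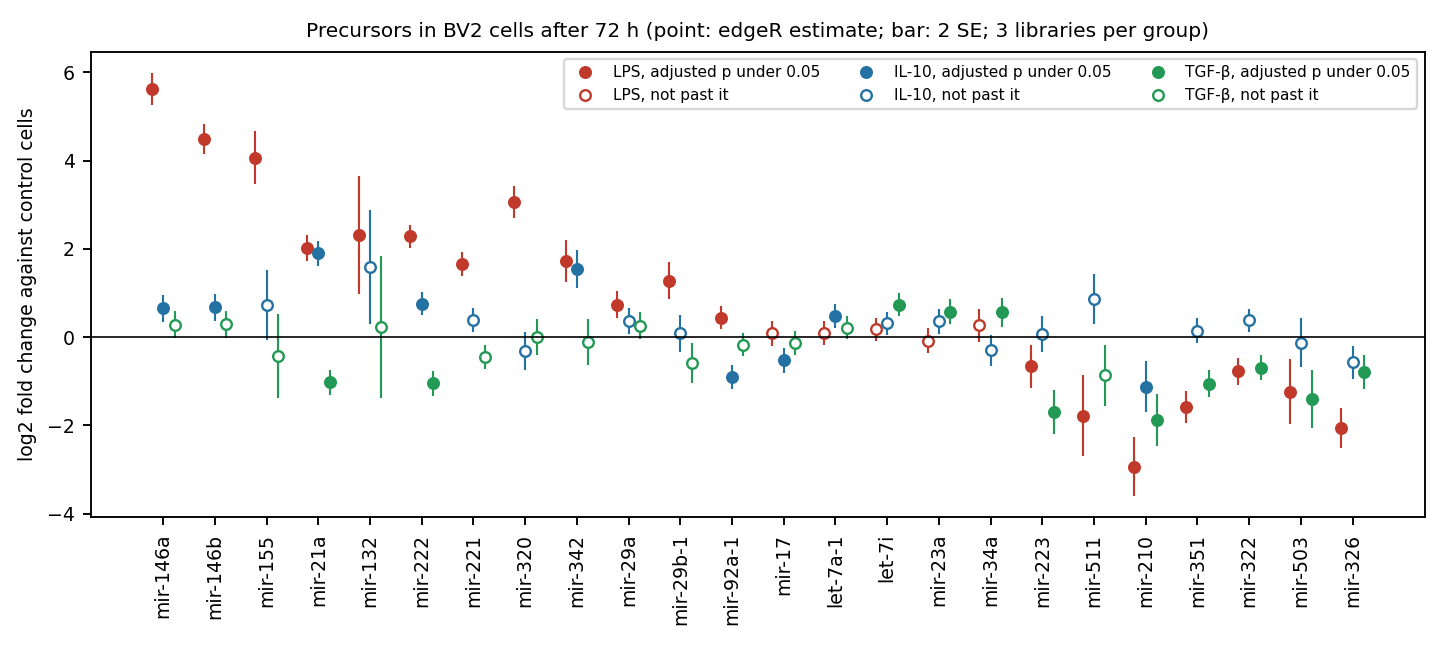
Log2 fold changes of 24 named precursors in BV2 cells after LPS, IL-10 or TGF-β, each against the 3 control libraries. Points are edgeR estimates, bars are 2 SE, and filled points passed an adjusted p of 0.05. mir-146a stood at 5.63 after LPS and 0.65 after IL-10, and mir-21a at 2.02, 1.90 and -1.03 after LPS, IL-10 and TGF-β.

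LPS was also set against the mean of the IL-10 and TGF-β groups, the contrast of a pro-inflammatory with cytokine-treated states. In cells mir-146a was higher after LPS by a log2 of 5.17 ± 0.13 (edgeR adjusted p = 1.67e-19; 3 LPS against 6 cytokine libraries), mir-146b by 4.01 ± 0.13, mir-320 by 3.23 ± 0.15 and mir-222 by 2.43 ± 0.11. The lower precursors were led by mir-700 (-1.60 ± 0.18), mir-326 (-1.39 ± 0.21), mir-351 (-1.12 ± 0.17), mir-328 (-0.93 ± 0.14) and mir-744 (-0.82 ± 0.13). All 5 members of the Toll-like receptor 4 and NF-kB list were higher (camera adjusted p = 2.15e-06; adjusted p = 0.314 with an estimated correlation), and 5 of 6 members of the miR-23/27/24 clusters were lower (6 adjusted over the list alone; camera adjusted p = 0.00525, adjusted p = 0.373 with an estimated correlation). In the former list mir-21a rose about as much after IL-10 as after LPS and fell after TGF-β. Its call here thus does not separate LPS from IL-10. Of 6 precursors overlapping rRNA, tRNA or snoRNA 5 were higher (6 adjusted over the list alone; camera adjusted p = 0.000677), of 4 miR-29 precursors 3 (4 adjusted over the list alone; 0.0274), and of 12 in the miR-17-92 list 5 (5 adjusted over the list alone; 0.0444). The list often reported as EV cargo had 4 of 11 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0265), and the myeloid list 4 of 9 higher and 1 lower, also the same (0.0299). The Sfmbt2 cluster had 1 of 67 higher and 16 lower (1 and 14 adjusted over the list alone; camera adjusted p = 0.0202). These 6 lists had an adjusted p = 0.373 with an estimated correlation. The let-7 family had 3 of 13 lower and 0 adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.502 with an estimated correlation). In total 57 precursors were higher and 51 lower, and with library totals, which moved the median from -0.01 to -0.23, 35 were higher and 76 lower.

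mir-210, mir-21a and mir-222 were called after each of the 3 treatments in cells. mir-210 was lower each time, and mir-21a and mir-222 were higher after LPS and IL-10 and lower after TGF-β. LPS and IL-10 shared 6 higher calls, where independent lists would share 2.92, among them mir-146a, mir-146b, mir-21a, mir-222 and mir-342. They had opposite calls for mir-92a-1 and mir-92a-2, whose LPS calls ended with library totals (0.02 and 0.03). LPS and TGF-β shared 6 lower calls, where independent lists would share 0.896: mir-210, mir-223, mir-322, mir-326, mir-351 and mir-503. mir-21a, mir-222 and mir-744 had opposite calls there. Part of any excess may come from the shared controls, whose 3 libraries cannot be split into parts of at least 2. Across 259 precursors the fold changes correlated at r = 0.181 for LPS and IL-10, 0.0101 for LPS and TGF-β and 0.343 for IL-10 and TGF-β. Simulated unchanged groups against shared controls gave mean values of 0.441, 0.421 and 0.481. The observed covariances were 0.0777, 0.00488 and 0.073, against simulated means of 0.0331, 0.0321 and 0.0329. In the EVs, over 71 precursors, r was 0.167, -0.156 and 0.572 for the same pairs, against simulated 0.479, 0.472 and 0.48, with covariances of 0.283, -0.297 and 0.574 against 0.403, 0.4 and 0.397.

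EVs were compared with the cells that released them, in controls, to see which precursors the vesicles held in other proportions. mir-6236 and mir-6240 were higher in EVs by a log2 of 8.72 ± 0.43 (edgeR adjusted p = 1.39e-14) and 8.10 ± 0.45. mir-6238 was higher by 7.24 ± 0.79, and both copies of mir-125b, a myeloid and neural precursor, by 5.49 ± 0.62. Several precursors were almost absent from control cells. mir-1a-1, a muscle precursor, had 37 counts over the 3 control EV libraries and 1 over the 3 control cell libraries, a ratio of 3260 after scaling (95% counting interval 549 to 132000). mir-203, an epithelial precursor, had 59 and 2 counts, a ratio of 2600 (687 to 21900), and mir-5108 had 84 and 1, a ratio of 7390 (1290 to 295000). mir-3544 (45 counts in EVs), mir-7000 (65) and mir-6345 (41) had no count in control cells, and with a floor of 3 counts over the group they were at least 1320-fold, 1910-fold and 1200-fold higher. These values hold for the scaling used, and the intervals leave out the spread between libraries. With library totals the bounds were 270-fold to 429-fold, and the ratios of mir-1a-1, mir-203 and mir-5108 were 732 (124 to 29700), 584 (155 to 4930) and 1660 (290 to 66400).

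The let-7 list was lower in EVs, with 7 of 13 members called and 9 adjusted over the list alone (camera adjusted p = 0.000881; adjusted p = 0.384 with an estimated correlation). let-7f-2 was at -1.69 ± 0.28, let-7a-1 at -1.52 ± 0.28 and let-7e at -1.43 ± 0.34. mir-98, of the same family, had 3 counts in control EVs and 2533 in control cells, a ratio of 9.6 in favour of cells (3.28 to 46.6). mir-5121 (-2.10 ± 0.34), mir-677 (-2.11 ± 0.34), mir-24-1 (-1.62 ± 0.36), mir-3535 (-1.70 ± 0.39) and mir-25 (-1.30 ± 0.31) were also lower. Of 59 tested members of the Sfmbt2 cluster 10 were lower, and none when adjusted over the list alone (camera adjusted p = 1.71e-06; adjusted p = 0.163 with an estimated correlation). They rest on few EV counts: mir-669o had 1 count in control EVs and 861 in control cells, a ratio of 9.79 (1.75 to 387), and mir-466b-4 had 2 and 856, a ratio of 4.86 (1.34 to 40.2). Many members of the cluster are numbered copies that may share reads, so its camera p may be too small. With library totals the ratios in favour of cells were 42.7 for mir-98 (14.6 to 207), 43.5 for mir-669o (7.79 to 1720) and 21.6 for mir-466b-4 (5.97 to 179). Precursors overlapping rRNA, tRNA or snoRNA were higher in 4 of 6 cases, the same adjusted over the list alone, with mir-1983 at 5.47 ± 0.73 and mir-664 at 3.89 ± 0.61 (camera adjusted p = 0.0222; adjusted p = 0.163 with an estimated correlation). mir-146a (1.50 ± 0.81) and mir-21a (-0.10 ± 0.48) were not called.

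In all 73 of 280 tested precursors were higher in EVs and 35 lower, and 162 (57.9%, chance 10%) had groups that did not overlap. DESeq2's size factors gave 80 higher and 8 lower, and library totals 55 and 170. The median of all tested precursors was -0.54, 0.28 and -2.68 under these 3 scalings, so directions here are relative to the scaling. With DESeq2's size factors mir-24-1 (-0.79), mir-3535 (-0.86), let-7e (-0.60), mir-25 (-0.46), mir-669o (-2.48) and mir-466b-4 (-1.47) were no longer called. The count was 68 without control cell library 2 and 70 without control cell library 3, against 108. Across 338 precursors the control EVs and cells correlated at Pearson's r = 0.33 and Spearman's rho = 0.317 in log2 CPM. These values use group means and leave out precursors with few counts, so they cannot be set beside r between replicates. Of the 72 precursors detected in control EVs, 53 were detected in control cells and 19 were not.

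**Figure D3:**
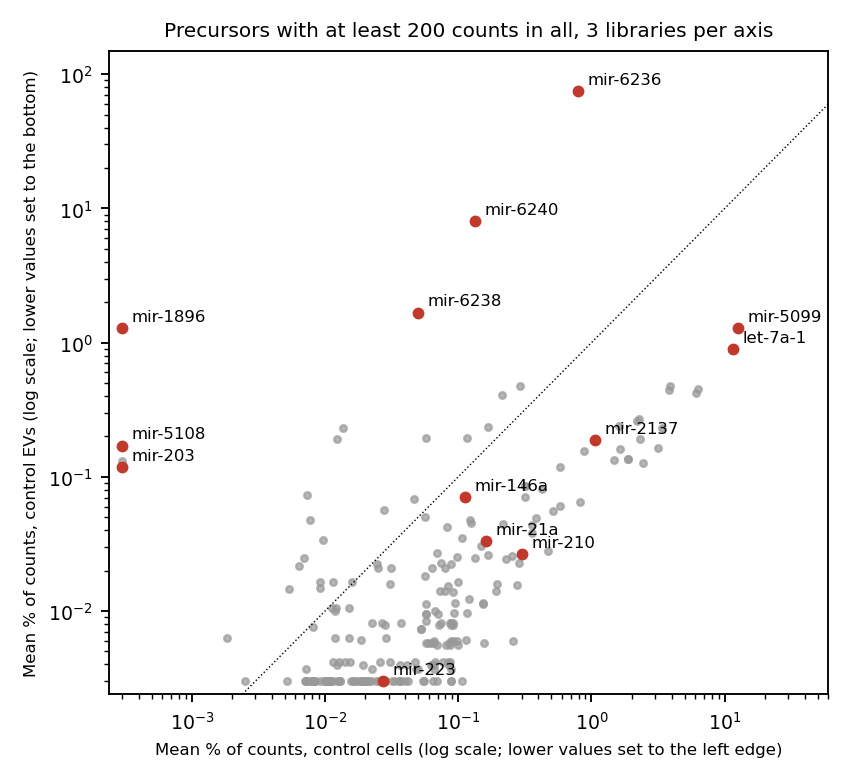
Mean percentage of counts per precursor in control EVs against control cells, both on log scales, for precursors with at least 200 counts over all libraries. Each point is a precursor averaged over 3 libraries per axis, with named ones in red and a dotted line of equal shares. mir-6236 lies at 74.5% in EVs and 0.796% in cells.

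After LPS 13 of the 71 precursors tested in EVs were called. Among changed precursors past the filter, simulated data gave back 20% of changes of log2 2 in this comparison and 2.55% of changes of log2 1. mir-2137 rose 5.89-fold, from 2118 ± 972 to 12507 ± 2585 normalised CPM (log2 2.56 ± 0.43, n = 3 each; edgeR adjusted p = 0.00386), and mir-5126 rose 6.09-fold (2.61 ± 0.80; edgeR adjusted p = 0.0386). mir-320 had 0, 0 and 2 counts in control EVs and 32, 97 and 94 in LPS EVs, a ratio of 34.1 after scaling (95% counting interval 9.32 to 283; edgeR adjusted p = 0.0103). mir-320 and mir-2137 were also higher in LPS cells, at 3.07 and 1.13 on the log2 scale. The falling precursors included the muscle precursor mir-1a-1 (-3.05 ± 0.64), the epithelial mir-203 (-2.65 ± 0.86), mir-5108 (-3.54 ± 0.73), mir-6345 (-3.61 ± 0.85), mir-3544 (-2.58 ± 0.69), mir-1896 (-2.63 ± 0.73), mir-3960 (-3.83 ± 1.02), mir-5100 (-4.99 ± 1.36), mir-6240 (-2.06 ± 0.48) and mir-5099 (-1.43 ± 0.38). mir-5100 had 77, 5 and 10 counts in control EVs, and without control EV library 1 it stood at -2.95 and was not called (edgeR adjusted p = 0.198).

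mir-146a, which rose 49.6-fold in LPS cells, had 19, 12 and 3 counts in control EVs and 14, 103 and 85 in LPS EVs (log2 0.67 ± 1.27, edgeR adjusted p = 0.756). mir-155 had 0, 0 and 0 counts in control EVs and 0, 1 and 2 in LPS EVs, so a change was not detectable at this depth, and mir-223 had no count in any of the 12 EV libraries. mir-21a was at 0.83 ± 0.84 (edgeR adjusted p = 0.55), let-7a-1 at 0.29 ± 0.26 (0.526) and mir-29a at 0.27 ± 0.92 (0.88). None of the 9 testable lists passed by camera in EVs after LPS, the smallest adjusted p being 0.236 for the list often reported as EV cargo, in which mir-320 was 1 of 4 members higher, also adjusted over the list alone. The totals were 3 higher and 10 lower, and 32 precursors (45.1%, chance 10%) had groups that did not overlap. The EV libraries after LPS had 26179 ± 2407 counts against 16648 ± 1214 in controls. Their share of mir-6236 was lower, at 57.2 ± 7.82% against 74.5 ± 1.17% in controls. With library totals, which moved the median from 0.02 to 1.10, 3 were higher and 1 lower, and 9 of the lower precursors were no longer called, among them mir-1a-1 (-2.02), mir-203 (-1.61) and mir-5108 (-2.40). With DESeq2's size factors, where the median was 0.22, mir-203 (-2.53) was not called either. The count of 13 fell to 1 without control EV library 1 or without LPS EV library 2, and to 2 without control EV library 2 or without LPS EV library 3.

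**Figure D4:**
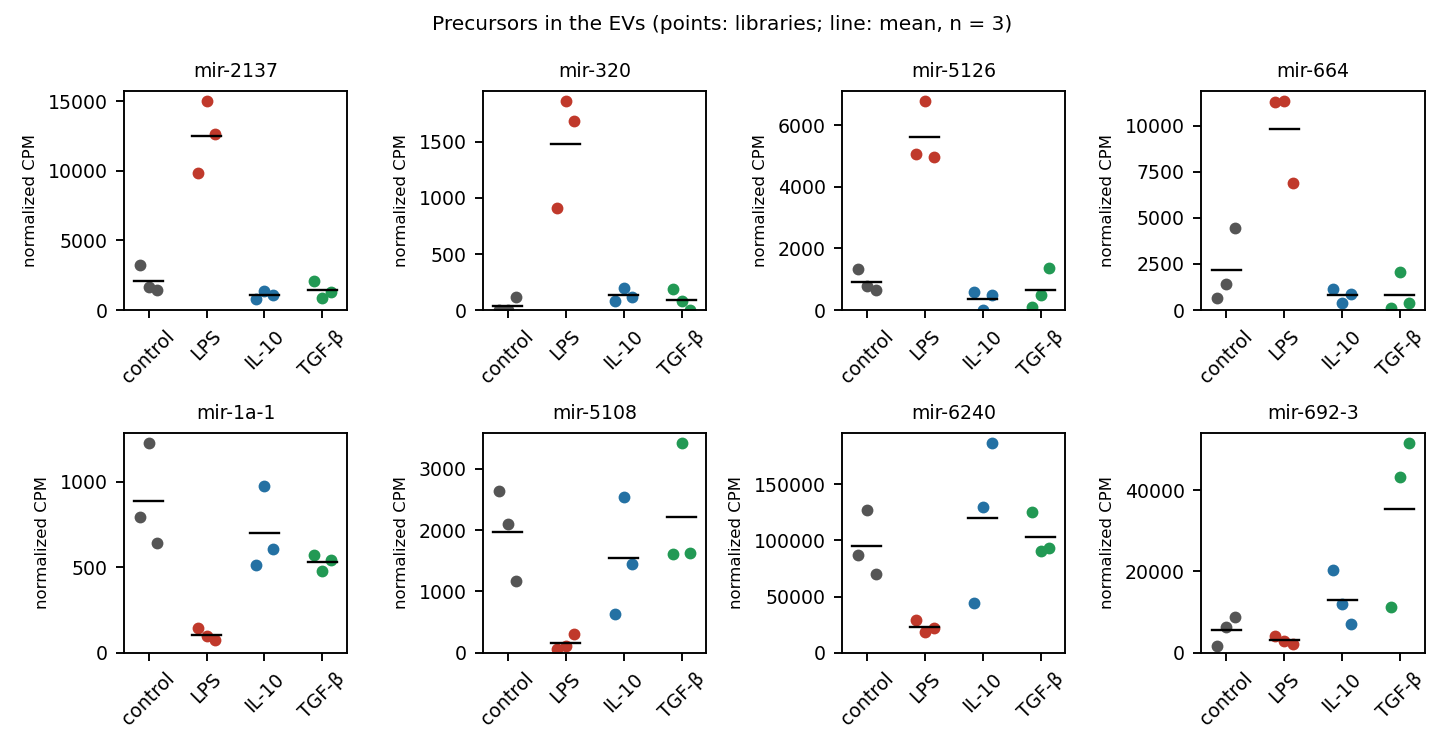
Normalised CPM of 8 precursors in EV libraries by treatment. Points are libraries and lines are means of 3. mir-2137 averaged 2118 in control EVs and 12507 in LPS EVs, and mir-692-3 averaged 5531 in control EVs and 35268 in TGF-β EVs, with wide spread between the TGF-β libraries.

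IL-10 changed no precursor in EVs past the threshold. The smallest p-values belonged to mir-682 (1.74 ± 0.60), mir-692-1 (1.62 ± 0.65) and mir-1931 (2.00 ± 0.99) on the higher side and mir-29a, let-7g (-1.85 ± 0.78) and mir-2137 (-0.97 ± 0.44) on the lower side, all with an edgeR adjusted p of 0.619 or above. mir-29a had 5, 1 and 16 counts in control EVs and 0, 1 and 1 in IL-10 EVs, so that most of its difference came from control EV library 3. mir-146a was at 0.76 ± 1.31, mir-21a at 0.28 ± 0.88 and let-7a-1 at 0.13 ± 0.26. edgeR and DESeq2 each called 0 of 71, with 5 and 7 at an unadjusted p under 0.05, and 7 precursors (9.86%, chance 10%) had groups that did not overlap. No list passed by camera.

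TGF-β raised 3 precursors in EVs, the copies mir-692-1 (2.88 ± 0.67), mir-692-2 (2.72 ± 0.69) and mir-692-3 (2.67 ± 0.68), each with an edgeR adjusted p of 0.0447. In normalised CPM all 3 TGF-β libraries lay above all 3 controls. As shares of library totals 2 copies overlapped: mir-692-3 had 117 and mir-692-2 107 of 16728 counts in TGF-β EV library 1, against 149 and 133 of 18047 in control EV library 3. mir-692-3 averaged 5531 ± 3660 normalised CPM in control EVs and 35268 ± 21321 in TGF-β EVs. Numbered copies of this kind cannot be counted as independent observations. mir-682 stood at 2.17 ± 0.60 (edgeR adjusted p = 0.061), mir-146a at -0.82 ± 1.38 (0.868) and mir-21a at -0.73 ± 0.94 (0.868). No list passed by camera, and 11 precursors (15.5%, chance 10%) had groups that did not overlap. With library totals, which moved the median from -0.18 to -0.46 (0.00 with DESeq2's size factors), the copies stood at 2.73 ± 0.84, 2.51 ± 0.84 and 2.47 ± 0.82, and the calls ended as the SE grew (edgeR adjusted p = 0.228). The calls also ended without any 1 of the 3 control EV libraries, TGF-β EV library 2 or TGF-β EV library 3, with values of 2.08 to 3.29. With 1 copy kept per set 0 were called.

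Against the mean of the IL-10 and TGF-β groups, LPS EVs had higher mir-2137 (3.34 ± 0.35; edgeR adjusted p = 2.81e-05), mir-320 (3.76 ± 0.76), mir-664 (3.54 ± 0.68), mir-5126 (3.49 ± 0.66) and mir-6238 (2.54 ± 0.68). They had lower mir-203 (-3.94 ± 0.84), mir-6345 (-3.93 ± 0.81), mir-5108 (-3.44 ± 0.69), mir-682 (-3.04 ± 0.58) and mir-6240 (-2.29 ± 0.45). In total 8 were higher and 17 lower, and with library totals, which moved the median from 0.19 to 1.31, 26 were higher and 8 lower. The count fell from 25 to 15 without LPS EV library 3. No list passed by camera.

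The effect of a treatment in EVs was tested against its effect in cells by an interaction term over all 24 libraries. For LPS, mir-6240 (-3.78 ± 0.49; edgeR adjusted p = 1.06e-05), mir-6236 (-2.13 ± 0.44), mir-5099 (-2.12 ± 0.41), mir-342 (-4.77 ± 1.05) and mir-5100 (-5.11 ± 1.15) changed less upward or more downward in EVs than in cells. The same held for mir-146a (-4.26 ± 1.08; edgeR adjusted p = 0.0173), which was chosen here after its values were seen. Without control EV library 1 mir-5100 (-2.78) and mir-5099 (-1.37) were not called. mir-5126 (3.21 ± 0.69), mir-93 (2.38 ± 0.67) and mir-2137 (1.98 ± 0.56) went the other way. Among 9 myeloid precursors 2 had a lower effect in EVs, mir-146a and mir-342 (4 adjusted over the list alone; camera adjusted p = 0.0311, adjusted p = 0.261 with an estimated correlation). In this list mir-223, mir-155 and mir-511 had no count in control EVs, so their fitted EV effects depend on the prior count. Of 59 members of the Sfmbt2 cluster 3 had a higher effect, the same adjusted over the list alone (camera adjusted p = 4.86e-05; adjusted p = 0.261 with an estimated correlation). These rest on few EV counts: mir-466d had 0, 1 and 0 counts in control EVs and 5, 20 and 25 in LPS EVs, and mir-466h and mir-669a-6, the latter chosen after its values were seen, had none in control EVs. Of the 59 members 13 had no count over the 3 control EV libraries and 28 had 1 to 3, so the fitted values of the list depend on the prior count. Many of the 59 are numbered copies that may share reads, so the camera p of the list may be too small. The totals for LPS were 7 higher and 10 lower. The split was 3 and 22 with DESeq2's size factors, and 56 and 7 with library totals, the median moving from 0.38 to -0.12 and 1.16. mir-2137 (1.45) and mir-93 (1.85) were not called with DESeq2's size factors, nor mir-5099 (-1.11) with library totals. It gave 32, 33 and 31 calls without control EV library 3, LPS EV library 1 and LPS EV library 2.

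For IL-10 and TGF-β edgeR called no difference between the effects in EVs and in cells, with 36 and 30 precursors at an unadjusted p under 0.05. The median SE of these log2 differences was 1.46 for IL-10 and 1.77 for TGF-β, so the absence of calls does not show equal effects. DESeq2 called 4 and 15, and edgeR with DESeq2's size factors 2 and 4. Those size factors moved the medians from -0.15 to 0.04 for IL-10 and from -0.14 to 0.03 for TGF-β, and library totals moved the latter to -0.43. The myeloid list was lower in the IL-10 difference, with 0 of 9 members called and 1 lower adjusted over the list alone (camera adjusted p = 0.000753; adjusted p = 0.0734 with an estimated correlation). The TGF-β responsive list, with 0 of 10 called and 0 adjusted over the list alone, had a camera adjusted p of 0.029 for IL-10 (adjusted p = 0.502 with an estimated correlation). In the myeloid list mir-223, mir-155 and mir-511 had no count in control EVs. In the TGF-β responsive list the same held for mir-155 and mir-199a-1. Fitted EV effects of such members depend on the prior count, so their differences may come from the cells alone.

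Markers of other cell types differed in abundance. In control EVs the neuron list took 0.24 ± 0.245% of counts, epithelium 0.122 ± 0.01%, muscle 0.114 ± 0.0428% and serum, red cell and liver 0.0425 ± 0.0736%, beside 0.32 ± 0.0349% for the myeloid list. In control cells these took 0.026 ± 0.00733%, 0.00213 ± 0.00205%, 0.000163 ± 0.000282%, 0.00207 ± 0.000354% and 0.644 ± 0.0459%. The epithelial mir-203 had 2 to 158 counts and the muscle precursor mir-1a-1 had 4 to 14 in each of the 12 EV libraries. The liver precursor mir-122 had at most 2 counts in any of the 12 cell libraries and none in the 12 EV libraries, the red cell precursor mir-451a had 1 count in 1 EV library, and the epithelial mir-200a had none. The red cell precursor mir-144 had 11 counts in control EV library 3, 25 in IL-10 EV library 1 and 1 in LPS EV library 1. mir-486a, also of red cells, had 12 counts in control EV library 3 and 3 in TGF-β EV library 2. The neuronal copies mir-124-1, mir-124-2 and mir-124-3 each had 12, 0 and 6 counts in control EVs. The same reads may have been counted for each copy, which would raise the share of the neuron list. Neither the neuron list nor that for endothelium and fibroblast passed by camera in any comparison that tested it. By single precursors, 2 of 3 tested neuron markers were called higher in control EVs than in control cells (camera adjusted p = 0.252, fry adjusted p = 3.62e-05). Of these, mir-124-2 had 12, 0 and 6 counts in control EVs and 1 over the control cells, a ratio of 1580 (250 to 66000), or 356 (56.3 to 14800) with library totals, and mir-128-1 (2.68 ± 0.84) stood at 0.493 with library totals and at -0.443 without control EV library 2, not called in either case. In LPS cells against the mean of the cytokines, the copies mir-128-1 (0.77 ± 0.27) and mir-128-2 (0.79 ± 0.26) were called higher (0.54 and 0.56 with library totals, not called). 3 of 4 markers of endothelium and fibroblast were called lower, mir-199a-1 (-0.73 ± 0.23), mir-199a-2 (-0.72 ± 0.24) and mir-199b (-0.71 ± 0.23). In this contrast the mir-128 and mir-199 precursors were chosen after their values were seen.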

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

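The tests of fewer mir-6236 and mir-6240 fragments, of a general rise of RNA fragments, of admixed RNA outside the let-7 family, of reads shared between copies and of single libraries were chosen only after the result was seen. The effect of LPS differed between EVs and cells, by the interaction test over 24 libraries, for 17 precursors. In log2, EVs minus cells, the difference was negative for mir-6240 (-3.78), mir-5099 (-2.12), mir-6236 (-2.13), mir-342 (-4.77), mir-5100 (-5.11), mir-3963 (-5.06), mir-146a (-4.26), mir-182 (-3.77), mir-1983 (-3.02) and mir-7a-1 (-1.95). It was positive for mir-5126 (3.21), mir-466d (4.47), mir-93 (2.38), mir-2137 (1.98), mir-466h (10.38), mir-185 (9.61) and mir-669a-6 (10.21). mir-466h, mir-185 and mir-669a-6 had no count in control EVs and mir-466d had 1, so that their fitted values depend on the prior count.

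In LPS EVs 48 of 69 tested precursors other than mir-6236 and mir-6240 (69.6%) took a larger mean share of counts than in control EVs. Admixed RNA of the releasing cells is argued against as the whole cause. The let-7 precursors imply an admixed fraction of 17.5 ± 4.24% (SE), and 2 of the 10 most abundant precursors of LPS cells lay more than 2 SE below it, mir-5099 at -1.47 ± 2.18% and mir-146a at 4.37 ± 2.45%. Of the other 8, 7 were let-7 members (13.8 to 21.3%), which are not independent of that value, and mir-3535 gave 10.5 ± 4.62%. Among the 20 most abundant precursors outside let-7, mir-6236 and mir-6240, 4 lay more than 2 SE below the let-7 value, mir-2137 lay above it (137 ± 34.9%), and 15 lay within 2 SE, so that admixture as a part of the cause stays open. Deeper libraries cannot be told apart from an LPS effect, since all 3 LPS EV libraries (23943 to 28727 counts) were deeper than the other 9 (15071 to 18047). In 1 library, IL-10 EV library 1, a similar composition (61.19% mir-6236, 9.326% let-7) occurred without LPS at 17724 counts. Thinning each EV library to 15071 counts left a median of 12 of 13 calls (9 to 13 over 20 draws), which decides nothing here, because thinning keeps the expected shares and 10 of the 13 calls were lower. Fewer mir-6236 and mir-6240 fragments beside unchanged other RNA cannot be told apart from a rise of the other RNA, because sequenced reads per library are not known; the mean count of the other precursors was 3.49 times that of control EVs, that of mir-6236 1.2 times and that of mir-6240 0.795 times. A response of the released RNA to LPS stays open and untested.

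In LPS cells 5 of 6 precursors overlapping rRNA, tRNA or snoRNA were higher. The lower depth of these libraries cannot be told apart from an LPS effect, since all 3 (185400 to 233757 counts) were shallower than the other 9 cell libraries. Thinning to 185400 counts, which keeps the expected shares, left a median of 5 calls (4 to 5) and decides nothing. A rise of all such fragments by 1 factor is argued against, since mir-6240 rose more than mir-6236 by a log2 of 0.969 ± 0.21 (SE). Whether LPS acts on these RNAs stays open, and no test of that was made.

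The 3 mir-692 copies were higher in TGF-β EVs. With TMM factors the higher level did not rest on any 1 library alone. This does not decide against single libraries as a cause, because the separation was seen before the test was chosen. All 3 TGF-β libraries lay above all 3 controls. With each of the 6 libraries left out in turn the copies stood at a log2 of 2.08 to 3.29, with the lowest at 2.08 ± 0.63 (SE). These values are not independent of the separation, which by itself makes them positive. As shares of library totals, TGF-β EV library 1 lay below control EV library 3 for mir-692-2 and mir-692-3, so the separation is limited to TMM factors for these 2 copies. The test of left-out libraries replaced, after its values had been seen, a count of lost calls. The calls ended without 5 of the 6 libraries, which fewer libraries alone can also do. Reads shared between copies were tested by the split of reads between 2 copies over 12 EV libraries. For mir-692-1 with mir-692-2 and with mir-692-3 the chi-square over degrees of freedom was 1.91 and 1.93, and shared reads cannot be told apart from separate copies there. For mir-692-2 with mir-692-3 it was 0.0715 (11 degrees of freedom), a more even split than separate reads would give. This argues against wholly separate reads for that pair. This test replaced a first one, the mean squared difference over the sum, after its values (22.63, 1.99 and 12.02) had been seen; all were above 1 and went against shared reads, but that measure also counts a constant difference in level between copies. An effect of TGF-β stays open.

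Other splits of the same libraries were counted for each comparison. For 3 against 3 libraries the 10 splits cannot give a share under 0.1. The real split called 83 precursors for LPS, 20 for IL-10 and 17 for TGF-β in cells, and the highest other split 0 in each case, so 1 of 10 splits gave as many. For LPS and TGF-β in EVs, with 13 and 3 calls, the highest other was also 0 (1 of 10 splits each). For EVs against cells the real split called 108 and the highest other 2 (1 of 10). For LPS against the mean of the cytokines 1 of 100 drawn splits gave as many in cells (108, highest other 85) and 1 of 100 in EVs (25, highest other 8). Both shares lay under the limit of 0.05 set beforehand, which argues against a random division of these libraries. A chance difference between cultures is not excluded, since the libraries of a group may be technical. For the difference of the LPS effects 2 of 100 drawn splits gave as many as 17. This share also lay under 0.05, but the highest other split called 29, more than the real one, so chance is not excluded there. Where edgeR called 0, any split gives as many and the count of splits says nothing: IL-10 in EVs (10 of 10 splits, highest other 1) and the differences of the IL-10 and TGF-β effects (100 of 100 splits, highest other 2 and 9).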

How the results depend on the processing

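Keeping 1 copy per set of numbered copies and leaving out mir-6236 and mir-6240 were chosen only after the data were seen. Of 2524 values of 166 called named precursors under the alternatives, 2145 kept direction and call, 370 lost the call and 9 reversed. With library totals the number of calls was 131 for LPS in cells, 4 for LPS in EVs, 0 for TGF-β in EVs, 225 for EVs against cells and 63 for the LPS difference between EVs and cells. At a mean of at least 50 counts, where fewer precursors are tested, it was 6 for LPS in EVs, 11 for LPS against the cytokines in EVs, 19 for EVs against cells and 3 for the TGF-β difference. Without a filter it was 197 for EVs against cells and 34, 4 and 3 for the LPS, IL-10 and TGF-β differences. DESeq2 gave 5 for TGF-β in EVs and 45, 4 and 15 for the differences, and its size factors 2 and 4 for the IL-10 and TGF-β differences. TGF-β in EVs had 0 calls with a robust prior, with only the 2 groups compared and with 1 copy per set, and 1 without mir-6236 and mir-6240. EVs against cells had 56 with only the control libraries and 171 averaged over 4 treatments. The LPS difference had 28 with 1 copy per set and 30 without mir-6236 and mir-6240. Leaving out 1 library at a time gave 65 to 86 calls for LPS, 5 to 21 for IL-10, 14 to 19 for TGF-β and 84 to 113 for LPS against the cytokines in cells. In EVs it gave 1 to 11, 0 to 0, 0 to 4 and 15 to 29. For EVs against cells it gave 68 to 136, and for the LPS, IL-10 and TGF-β differences 13 to 33, 0 to 1 and 0 to 4. With an estimated correlation 0 lists were called. Thinning, which lowers depth, left 144, 130, 144 and 136 detected precursors in control, LPS, IL-10 and TGF-β cells. At 1 count or more EVs held 205, 250, 173 and 157, both controls shared 162, and 43 were in control EVs without control cells. At a mean of at least 50 counts r between treatment effects was 0.313, 0.178 and 0.171 in cells and -0.551, -0.507 and 0.906 in EVs, for LPS with IL-10, LPS with TGF-β and IL-10 with TGF-β. Simulated unchanged groups against shared controls gave means of 0.474, 0.474 and 0.497 in cells and 0.457, 0.498 and 0.471 in EVs. Reversed values were mir-16-2 after LPS in cells with library totals (-0.00569) and, for EVs against cells, mir-29a with library totals (-0.929) and without control EV library 3 (-0.538), mir-18a without control EV library 3 (-6.86) and mir-128-1 without control EV library 2 (-0.443). Over the libraries left out in turn mir-29a ranged from -0.538 to 1.71, mir-18a from -6.86 to 2.85 and mir-128-1 from -0.443 to 2.65. Averaged over 4 treatments mir-18a (-0.107), mir-29a (-0.0937), mir-342 (-0.282) and mir-128-1 (-1.04) reversed as well. Except where fewer precursors, libraries or counts are named, the cause was not tested. No paired analysis was possible because the column numbers match no label. At a log2 change of 2 simulated data gave back 20% of the changed precursors past the filter for LPS in EVs, against 98.4% in cells. The simulation does not separate depth from the spread between replicates.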

Other observations

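A set of 14 precursors had at least 20 counts over the 12 EV libraries and at most 3 over the 12 cell libraries, and all were chosen after their values were seen. mir-6345 (139 counts) and mir-3544 (148) had counts in each of the 12 EV libraries, mir-5119 (187) and mir-8117 (60) in 11, and mir-6990 (64) in 10. mir-144, a red cell precursor, had 37 counts in 3 EV libraries. The others were mir-708 (41), mir-6336 (46), mir-5124a (33), mir-1264 (33), mir-6979 (25), mir-5112 (25), mir-5709 (21) and mir-3100 (21).

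Precursors encoded close together were tested for a shared change in cells, a test planned before its result was seen. Among 258 tested precursors with a position, 50 pairs of 44 precursors lay within 10 kb in GRCm38. The mean product of their standardized log2 fold changes was 0.336 after LPS (95th percentile of 10000 random reassignments 0.219, permutation p = 0.0187, adjusted p = 0.0333), 0.302 after IL-10 (0.222, permutation p = 0.0222, adjusted p = 0.0333) and 0.201 after TGF-β (0.231, permutation p = 0.0666, adjusted p = 0.0666). Of the 50 pairs 32, 28 and 28 changed with the same sign. Neighbours may thus have changed together after LPS and IL-10, while for TGF-β the value lay below the percentile. Pairs with the same number in their names and pairs within the Sfmbt2 cluster were left out, a choice that the planned test did not contain. Related pairs with different numbers stayed in, such as mir-98 with let-7f-2, mir-15a with mir-16-1 and mir-16-2 with mir-15b. Overlapping pairs make these p-values too small.

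Numbered copies of one precursor had counts closer to each other than in 95% of 1000 simulated even splits of separate reads in 27 of 178 pairs in cells, where chance gives 8.9, and in 8 of 15 in EVs, where chance gives 0.75. This test was chosen after the values were seen, and pairs that share a copy are not independent. Reads counted for both copies would bring counts this close, and for the remaining pairs the test does not show it.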
